A study of Mus musculus with 4 samples.

How the data were processed

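RNA from the tibialis cranialis muscle of mice on a high fat diet was measured on Affymetrix GeneChip arrays of the mouse genome. Per the labels, each array carried a mixture of equal amounts of RNA from 4 animals, RNA was extracted with Tri-reagent, and labelled extracts were made with the Nugen Ovation V2 and Encore Biotin kits. The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes; the versions are not given in the sources used here. The labels do not state the log base. The values ran from -0.45 to 13.1, and a natural logarithm would place the top above the range of a scanner, so they were read as log2. Array medians of 1.06 to 1.11 and values below 0 are low for RMA, so a background or scale step not given in the sources cannot be excluded, and the printed fold values hold on the deposited scale.

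The table held 45101 probe sets, of which 34958 had 1 gene symbol, 932 had several and 9211 had none in the probe table; the 64 array controls were left out of every test. No gene was named from a probe set with several symbols or none, so some genes, Mstn (the myostatin gene) among them, were not analysed here. Symbols were looked up by gene identifier in a RefSeq table of assembly GRCm38.p6: 34754 probe sets matched, no symbol changed, and 204 kept the symbol of the probe table. Each named gene was represented by its brightest probe set, by the mean over the 4 arrays, and probe sets with a mean below the 25th percentile (0.45) were left out, which left 15103 genes; 6897 of them had more than 1 probe set above that level. No further normalization was applied. Arrays have no read depth. Their number, 2 per group, limits the precision, and the median standard error of a difference was 0.19 on the log2 scale.

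All 4 arrays entered the main fits. ProMyo was compared with saline in limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with Benjamini-Hochberg adjustment and a threshold of 0.05; the fit had 2 residual degrees of freedom and 3.16 prior ones. Genes with a difference of at least 1.5-fold in the same direction in both pools of animals were counted without a test, and the same count was made for the other 2 ways of parting 4 arrays into pairs. For 38 gene lists, 37 of which had at least 3 measured genes, limma's camera compared the list with all other genes at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The lists held 763 genes, 686 of them measured, and covered muscle fibre types, the myostatin and growth pathways, protein turnover, metabolism, connective tissue and the other cell types that whole muscle can hold. Both muscles came from the same 8 mice, and pools of both groups carry the same animal numbers, so the pools were taken as paired by the design. The main fit compared the groups without this pairing, so its p-values and all printed standard errors include differences between animals. The deviations of same-numbered pools from their group means correlated with r = 0.16 across genes.

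The groups, the tests, the filter, the lists, the named genes and all alternatives, except the counts of 1.5-fold changes without an array, were fixed before the data were examined. The named genes were Mstn, Fst, Acvr2b, Acvr2a, Smad3 and Gdf11; the 10 genes with the highest and the 10 with the lowest difference past the threshold, filled up with the largest differences of at least 1.5-fold in both pools, predicted and small RNA genes aside; up to 4 members with the smallest p in each list reported; and the members behind a count of 5 or fewer. Alternatives were the pool as a block, no filter, a filter at the 50th percentile, 2 variance models with trend, median-centred arrays, quantile normalization, the mean of a gene's probe sets, every probe set in place of genes, other thresholds, other set tests, and leaving out each array. On 20 sets of simulated arrays with 200 changed genes among 15103, the gene test recovered 0% of 1.5-fold, 0.9% of 2-fold, 72% of 4-fold and 92% of 8-fold changes, with 4.85 false calls on average. In the same simulations of ProMyo against saline over 15103 genes, camera was given a list of 31 proteasome genes shifted by 0.15. It called this list in 5 of 20 sets with the preset correlation and in 0 with the estimated one. The simulated genes varied independently of each other, so these sets do not show the effect of correlation within a list.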

Results

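Expression was measured in the tibialis cranialis, a muscle at the front of the lower hind leg, of 8 male C57Bl/6 mice on a high fat diet. The diet began at 8 weeks of age. At 4 weeks on the diet, AAV8 ProMyo was injected into this muscle in 1 leg and saline into the same muscle of the other leg, and both muscles were taken 10 weeks later, when the mice were 22 weeks old. AAV8 is an adeno-associated virus that transduces muscle fibres well, and ProMyo is the propeptide of myostatin, which binds and blocks this inhibitor of muscle growth. The 8 mice were combined into pools of animals 1-4 and 5-8, which gave 2 arrays of ProMyo muscle and 2 of saline muscle, each a mixture of RNA from 4 animals. Array medians lay between 1.06 and 1.11 on the log2 scale. The saline 5-8 array had an upper quartile of 2.98, against 3.15 to 3.20 in the other 3, and its spiked-in hybridization controls averaged 11.1 against 10.1 to 10.2. The Bacillus controls, for which no target was expected, reached 0.99 at most and marked the background level for all arrays. Their maximum was 0.99 in saline 5-8, 0.76 in saline 1-4, 0.68 in ProMyo 1-4 and 0.57 in ProMyo 5-8.

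The comparison of both legs addresses what AAV8 ProMyo changes in muscle gene expression under a high fat diet. The control leg received saline and no empty vector, so the comparison does not part myostatin inhibition from the vector. At camera's preset correlation of 0.01, genes of the extracellular matrix and of tendon were called lower in ProMyo muscle, with median log2 differences of -0.17 and -0.28. Proteasome subunits and genes of fatty acid uptake and oxidation were called higher, with medians of 0.15 and 0.19. The estimated correlation between members was 0.255 in the proteasome list and 0.414 in the fatty acid list, against 0.06 for matrix and -0.023 for tendon. If those estimates hold, the preset p-values of the proteasome, fatty acid and matrix lists are too small. The matrix estimate, though smaller, also lies above the preset 0.01. With an estimated correlation none of the 37 lists passed camera's test (smallest adjusted p = 0.95). That setting rests on 2 residual degrees of freedom. In simulated arrays of independent genes it called a list shifted by 0.15 in 0 of 20 sets, and the preset correlation called it in 5. The estimated setting therefore has little power for such a shift and does not show whether correlation between genes produced the other preset calls. The tendon estimate lay below the preset 0.01. The loss of the tendon call (camera, unadjusted p = 0.00019 preset and 0.059 estimated) therefore did not come from a higher correlation. No named gene passed limma's test by itself: 0 of 15103 genes had an adjusted p under 0.05 (smallest adjusted p = 0.82), 874 had an unadjusted p under 0.05 where chance gives 755 and the other 2 partings of the arrays gave 969 and 389, and limma with the paired pools as a block also called 0 genes, with 1039 at an unadjusted p under 0.05. In simulations of this comparison the gene test recovered 0.9% of 2-fold and 72% of 4-fold changes. The largest difference was at a probe set to which no gene name was attached here. What this probe set detects was not analysed, so it is not shown to read a transcript of the muscle's own genes. Its log2 value was 10.0 ± 0.61 (SD, n = 2) in ProMyo muscle, with 10.43 and 9.57 in the single arrays, and 0.77 ± 0.03 (SD, n = 2) in saline muscle, within the range of the background controls. It was the 1 probe set past the threshold when limma was run on all 33787 probe sets above the filter (adjusted p = 0.0169).

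Extracellular matrix genes were lower in ProMyo muscle in both pools for 22 of 37 measured members and higher in both for 5 (camera, adjusted p = 0.0035; adjusted p = 0.95 with an estimated correlation). The fibrillar collagen chains Col1a2 and Col1a1, which together form type I collagen, differed by -0.78 ± 0.15 and -0.68 ± 0.18 (log2 ± SE, n = 2 pools per group), which put saline muscle 1.71-fold and 1.60-fold above ProMyo muscle. The next brightest probe sets read -0.35 for Col1a2 and -0.88 for Col1a1. Mmp2, a matrix metalloproteinase, differed by -0.57 ± 0.20. Timp1, an inhibitor of such proteases, differed by -0.69, from 1.19 in saline muscle to a level within the background controls. The size of the Timp1 difference is therefore uncertain. Lum, the small proteoglycan lumican, went the other way with 0.63 ± 0.25. Tendon markers were lower in both pools for 7 of 12 measured members and higher in both for 1 (camera, adjusted p = 0.0035; adjusted p = 0.95 with an estimated correlation). Chad (chondroadherin) differed by -1.24 ± 0.28, Fmod (fibromodulin, a collagen-binding proteoglycan) by -0.53 ± 0.16, Prg4 (lubricin) by -0.53 ± 0.20 and Cilp by -0.34 ± 0.18. In neither list did a member pass the threshold, over all genes or adjusted over the list alone. The 16 fibroblast markers, of which Lum and Dcn are also matrix genes, had a median of -0.08 (camera, adjusted p = 0.47). The fry test called them changed in either direction (adjusted p = 0.00054). In both pools 7 of them were lower and 5 higher. Pi16 stood at -0.96 ± 0.20, Gsn at -0.31 ± 0.16 and Thy1 at -0.35 ± 0.18, and Lum, as above, was higher. Of the macrophage markers, C1qb stood at -0.48 ± 0.17, Mrc1 at -0.45 ± 0.17 and Cd163, the other way, at 0.37 ± 0.19. The macrophage list had a median of -0.17, with 14 of 25 members lower in both pools and 3 higher in both. It missed the threshold in the main comparison (camera, adjusted p = 0.064) and passed it with the paired pools as a block (adjusted p = 0.031; adjusted p = 0.95 unpaired with an estimated correlation); its median was -0.07 without the ProMyo 5-8 array and -0.09 without the saline 1-4 array. Without the saline 1-4 array the matrix median was -0.10 (adjusted p = 0.028). Without the saline 5-8 array it was -0.23 (adjusted p = 0.024) and the tendon median -0.22 (adjusted p = 0.21), and without the ProMyo 1-4 array they were -0.18 (adjusted p = 0.24) and -0.31 (adjusted p = 0.034).

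Proteasome subunits were higher in ProMyo muscle in both pools for 22 of 31 measured genes and lower in both for 1 (camera, adjusted p = 0.0055; adjusted p = 0.95 with an estimated correlation). Psma4, a subunit of the core particle, differed by 0.60 ± 0.19, and the regulatory particle subunits Psmd7, Psmd6 and Psmc1 by 0.54 ± 0.19, 0.43 ± 0.16 and 0.40 ± 0.17. Genes of fatty acid uptake and oxidation were higher in both pools for 17 of 31 measured genes and lower in both for 3 (camera, adjusted p = 0.025; adjusted p = 0.95 with an estimated correlation). Etfb and Etfdh, which pass electrons from fatty acid oxidation to the respiratory chain, differed by 0.64 ± 0.17 and 0.40 ± 0.16, Acadl, a dehydrogenase of long-chain acyl-CoA, by 0.35 ± 0.15, and Slc25a20, the mitochondrial carnitine-acylcarnitine carrier, by 0.33 ± 0.18. The mean of both probe sets of Etfdh read -0.28, with the other probe set near the background controls. No member of either list passed over all genes or adjusted over the list alone. Without the saline 5-8 array, the proteasome median was 0.10 (adjusted p = 0.079) and the fatty acid median 0.10 (adjusted p = 0.40); without the ProMyo 1-4 array they were 0.12 (adjusted p = 0.24) and 0.06 (adjusted p = 0.64), and the fatty acid list also missed the threshold with quantile normalization (median 0.11, adjusted p = 0.076) and with the filter at the 50th percentile (median 0.19, adjusted p = 0.068). The 44 measured genes of oxidative phosphorylation had a median of 0.04 and the 19 of the citrate cycle 0.11 (camera, adjusted p = 0.95 and 0.47). Dlst, of the 2-oxoglutarate dehydrogenase complex, stood at 0.46 ± 0.15 while the mean of its probe sets read -0.12, and fry called the citrate cycle list changed in either direction (adjusted p = 0.012). The signal of the 3' probe sets over the 5' probe sets, a measure of RNA integrity and amplification, was 0.66 log2 units for Gapdh in ProMyo muscle and 0.85 in saline muscle, and 1.68 and 1.88 for Actb. Single arrays read 0.58 and 0.74 in ProMyo muscle and 0.90 and 0.81 in saline muscle for Gapdh. For both genes both ProMyo arrays lay below both saline arrays. Whether this affects the lists was not tested.

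**Figure D1:**
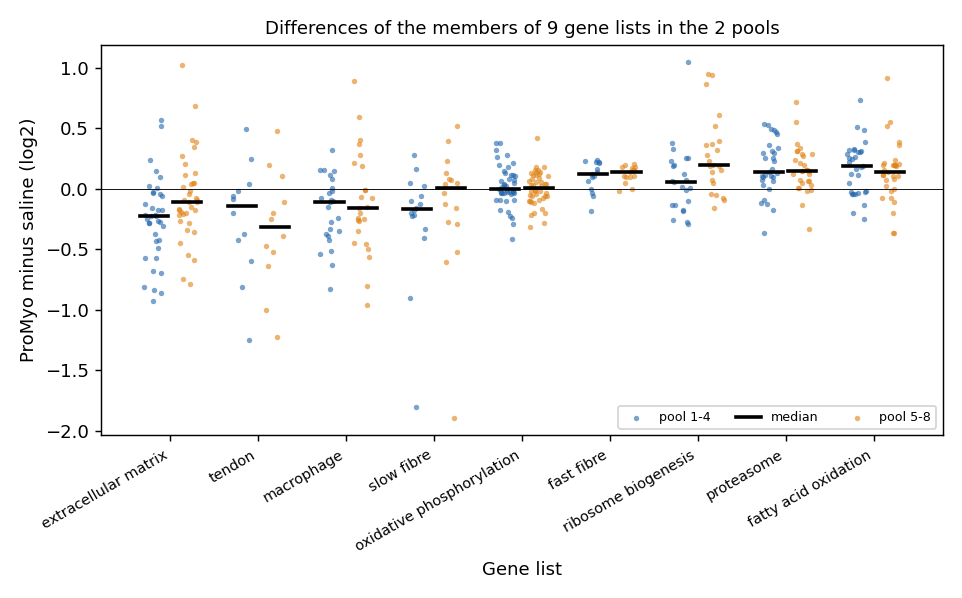
ProMyo minus saline differences (log2, vertical axis) of the members of 9 gene lists (horizontal axis), with 1 point per gene in pool 1-4 (blue) and in pool 5-8 (orange) and a black line at each median. The matrix medians were -0.23 and -0.11 in the 2 pools, the tendon medians -0.15 and -0.32, the proteasome medians 0.14 and 0.15, and the fatty acid medians 0.19 and 0.14.

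Among the genes of the myostatin pathway, the receptor genes Acvr2b and Acvr2a differed by 0.50 ± 0.28 and 0.08 ± 0.15, the signal transducer Smad3 by 0.25 ± 0.17, and Fst (follistatin, which binds myostatin) by -0.54 ± 0.27 (limma, adjusted p between 0.83 and 0.95). Acvr2b was dim, at 1.31 in the saline 1-4 array and 0.61 in the saline 5-8 array, the latter within the background controls. The difference of Fst was -0.96 in pool 1-4 and -0.12 in pool 5-8. Fstl3, another binding protein of this family, stood at -0.70 ± 0.27. Other probe sets above the background controls read 0.07 at Acvr2b, 0.03 at Smad3 and -0.01 at Fst. The mean of the probe sets of Smad3 read -0.23, with 1 of them within the background controls. Gdf11 was below the filter on dim probe sets and was not tested. The 21 measured members of the pathway had a median of -0.03 (camera, adjusted p = 0.95).

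Genes of slow fibres had a median of -0.10, with 7 of 16 members lower in both pools and 3 higher in both (camera, adjusted p = 0.21, and 0.95 with an estimated correlation). The median was -0.17 in pool 1-4 and 0.002 in pool 5-8. Myl2, the slow regulatory light chain, had the lowest difference of the named genes with -1.85 ± 0.65. Its levels spread from 3.43 to 1.95 between the ProMyo pools and from 5.23 to 3.84 between the saline pools. The differences within pools 1-4 and 5-8 were close, at -1.80 and -1.89, so the standard error of the unpaired fit reflects the spread between pools of animals. Csrp3, a muscle LIM protein, stood at -0.71 ± 0.23, and Myl3 and Tnnc1 at -0.35 ± 0.19 and -0.24 ± 0.16. The fast fibre list had a median of 0.13, with 11 of 15 members higher in both pools (camera, adjusted p = 0.21), Mylpf and Actn3 each at 0.21, with standard errors of 0.15 and 0.17. The myosin heavy chains Myh2 (type 2A) and Myh1 (type 2X) stood at -0.39 ± 0.19 and 0.05 ± 0.15; with 2 genes their list was not tested.

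Of the genes with the largest differences, those lower in ProMyo muscle were Myl2, Chad, Kcnd2 (-1.21 ± 0.28), Mss51 (-1.16 ± 0.23), Btbd11 (-1.10 ± 0.17), Nipal3 (-1.04 ± 0.21), Lrrc27 (-1.02 ± 0.24), Ccdc80 (-1.01 ± 0.15), Tmem86a (-1.01 ± 0.22) and Fam20c (-1.00 ± 0.35). Mss51 encodes a mitochondrial protein of skeletal muscle, and Fam20c a kinase of secreted proteins. Those higher were Gabrb1 (1.57), Invs (1.55), Zfp982 (1.49 ± 0.34), Wdr41 (1.47 ± 0.48), Elf1 (1.35 ± 0.19), Car8 (1.35 ± 0.40), Mup10 (1.32 ± 0.34), Actc1 (1.30 ± 0.31), Top2a (1.29 ± 0.26) and Foxc1 (1.26 ± 0.23). None of these 20 passed the threshold (limma, adjusted p = 0.82 for each). Actc1, an actin of heart and of embryonic skeletal muscle, was at 5.96 ± 0.53 in saline and 7.26 ± 0.33 in ProMyo muscle (SD, n = 2). At the probe sets used, Gabrb1 and Invs were within the background controls in saline muscle, so their saline levels are uncertain. Since they were also picked by size, their differences do not bound the true change. Of the other probe sets of these genes that were above the background controls, several did not share the difference: it was 0.05 at Elf1, -0.02 at Wdr41, 0.03 at Invs, 0.29 at Zfp982, 0.25 at Kcnd2 and -0.23 at Btbd11. At Top2a, a DNA topoisomerase of dividing cells, it was 0.80. The other probe sets of Gabrb1, Car8 and Foxc1 were within the background controls and decide nothing.

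**Figure D2:**
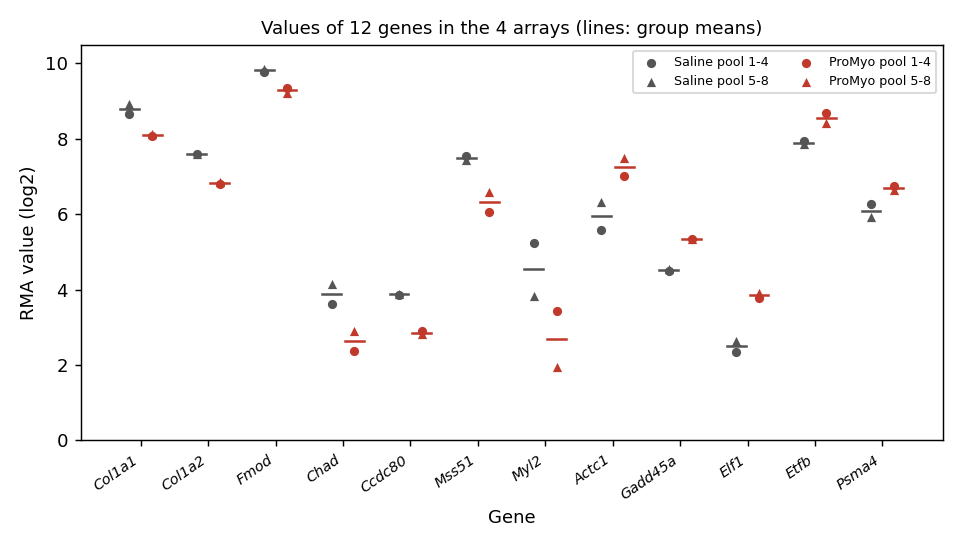
Log2 RMA values (vertical axis) of 12 named genes (horizontal axis) in the 4 arrays, with saline in grey, ProMyo in red, circles for pools 1-4, triangles for pools 5-8 and lines at the group means. Both ProMyo values of Col1a1, Col1a2, Fmod, Chad, Ccdc80, Mss51 and Myl2 lie below both saline values, and those of Actc1, Gadd45a, Elf1, Etfb and Psma4 above them; Col1a2 has group means of 6.82 and 7.60, and Gadd45a of 5.35 and 4.53.

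In both pools 241 genes differed by at least 1.5-fold in the same direction, 156 higher and 85 lower in ProMyo muscle, and 23 differed by at least 2-fold. Parting the same arrays by pool, animals 1-4 against animals 5-8, gave 254 genes, and the crossed parting gave 90, where each difference lies between different animals. Within the pools 93 genes differed by at least 1.5-fold in opposite directions. Across genes, the differences of the 2 pools correlated with a Pearson r of 0.15 and a Spearman rho of 0.14, and 53.1% of genes had the same sign in both; genes are not independent replicates. Quantile normalization gave 235 genes, 123 higher and 112 lower, so that the share of higher genes went from 64.7% to 52.3%. In 41 of the 241 genes, 1 or both groups lay within the background controls. Without the saline 5-8 array, 610 genes were at least 1.5-fold apart from the saline 1-4 array in both ProMyo arrays, 262 higher and 348 lower, and 173 of them were among the 241; without the saline 1-4 array there were 1095, without ProMyo 1-4 there were 528 and without ProMyo 5-8 there were 421, where both differences share 1 array.

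**Figure D3:**
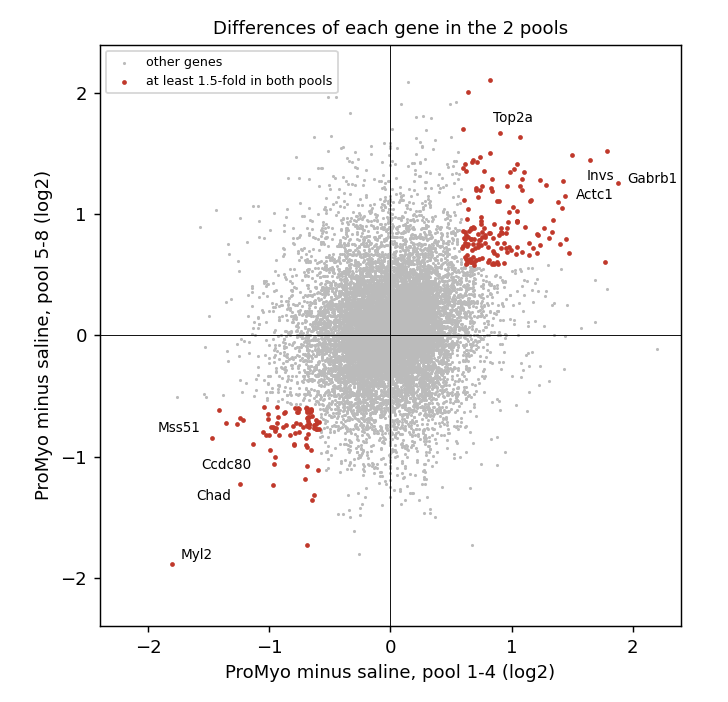
ProMyo minus saline differences (log2) of 15103 genes in pool 1-4 (horizontal axis) and pool 5-8 (vertical axis), with the 241 genes of at least 1.5-fold difference in both pools in red. The cloud is nearly round, with a Pearson r of 0.15 across genes, and Myl2, at -1.80 and -1.89, lies at the lower left.

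Genes of growth and protein breakdown gave small medians. Ribosome biogenesis genes were higher in both pools for 11 of 23 members, with a median of 0.13 (camera, adjusted p = 0.056; adjusted p = 0.95 with an estimated correlation), which was 0.30 without the saline 1-4 array and 0.06 without the saline 5-8 array, and Nop58, a core protein of nucleolar ribonucleoproteins, stood at 1.00 ± 0.18. Nop58 was the 1 gene of the fixed lists to pass when adjusted over the list alone (limma, adjusted p = 0.0496). This adjustment was made within each of 38 lists, so a single pass this near the threshold carries little weight. It did not pass over all genes. The ubiquitin and atrophy list had a median of 0.02 (camera, adjusted p = 0.80, direction down), with Gadd45a, induced in atrophying and denervated muscle, at 0.82 ± 0.15, and the metallothioneins Mt1 and Mt2 at -0.83 ± 0.27 and -0.67 ± 0.22. The medians were 0.07 for insulin and mTOR signalling, -0.08 for autophagy and 0.10 for polyamine genes (camera, adjusted p = 0.78, 0.80 and 0.78). The polyamine median was -0.19 without the saline 5-8 array and 0.22 without the saline 1-4 array.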

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

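The tests of the fibroblast markers, of the next brightest probe sets, of opposite directions within the pools and of the lists in the other partings were chosen after the result was seen. Gene counts in the other partings and the lists without each array were planned, but their use as tests of an explanation was chosen after the result was seen. Probe sets with no gene name, which no comparison of named genes used, held signals above those of saline muscle. In 1 of them ProMyo muscle was 9.23 log2 units above saline muscle (limma, adjusted p = 0.0169 over 33787 probe sets), and the next smallest adjusted p was 0.77. Its saline values, 0.75 and 0.79, lay within the background controls, so the size of this difference is uncertain. Since the probe set was picked by size, the difference does not bound the true change. No explanation was tested for this probe set.

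Of 6623 probe sets without a single gene name above the filter, 258 were at least 1.5-fold higher in ProMyo muscle in both pools and 24 lower, so that 91.5% were higher. Parting the arrays by pool gave 198 such probe sets, 36 and 162 in the 2 directions, and the crossed parting 43, and within the pools 43 went in opposite directions. The saline 5-8 array, with its brighter controls, is argued against as the sole cause: without it 452 of 551 probe sets, or 82.0%, were higher. Low brightness is argued against too, since 67.3% of named probe sets were higher when weighted to the same brightness. What these probe sets detect was not analysed here, so an effect of the treatment on transcripts outside the named genes stays open, untested, as may other differences between the arrays.

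The 241 genes with at least 1.5-fold difference in both pools may owe a part to differences between arrays that are unrelated to the treatment. The other partings, with 254 and 90 genes, set different animals against each other and do not decide this; within the pools 93 genes differed in opposite directions, and 2 pools are too few to exclude a difference that both ProMyo arrays share. A further candidate explanation is signal of single probe sets: in the 73 of these genes with another probe set brighter than the background controls, that probe set moved by a median of 0.088 in the direction of the brightest one (SD 0.36), against 0.84 for the brightest, and 2 of 73 also reached 1.5-fold in both pools. Some regression towards 0 is built into a choice by size. An effect of the treatment on a part of the genes stays open.

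For the 4 shifted lists, which camera called with the preset correlation but not with an estimated one (adjusted p = 0.95) and fry did not call, an uneven spread of values between the arrays is argued against for the matrix and tendon lists, with medians of -0.22 and -0.32 after quantile normalization (adjusted p = 0.0013 and 0.0072), and left open for the proteasome and fatty acid lists, with 0.093 and 0.11 (adjusted p = 0.036 and 0.076). The saline 5-8 array alone does not account for the matrix list, whose median without it was -0.23 (adjusted p = 0.024), whereas the tendon, proteasome and fatty acid lists, with medians of -0.22, 0.10 and 0.10 without it (adjusted p = 0.21, 0.079 and 0.40), do not settle the point. Fewer connective tissue cells in the ProMyo samples may also lower matrix genes: fibroblast markers outside the matrix list had a median of -0.10, between 0 and the matrix median, with members in both directions. In the other 2 partings of the arrays camera called 0 lists, with 2 and 1 lists at an unadjusted p under 0.05, against 4 and 8 in the real one, and the first of the 2 sets different animals against each other; 3 partings are too few for a share under 0.05. An effect of the propeptide or of the vector on these genes stays among the open explanations. So does a difference in RNA integrity or amplification, which was not tested. The 3' over 5' signal of Gapdh and Actb was lower in both ProMyo arrays than in both saline arrays.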

How the results depend on the processing

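The counts of 1.5-fold genes without an array were chosen after the data were seen; the other alternatives were planned. limma called 0 genes under the replicate block for the paired pools, both filters, both variance models, both normalizations, the mean of probe sets, an adjusted p under 0.1 and each array left out, and 1 probe set, without a gene name, when every probe set was tested. The 241 genes of at least 1.5-fold became 148 with the mean of probe sets, 740 with every probe set (33787 features in place of 15103 genes), 23 at 2-fold, 744 by the mean difference alone, and 421 to 1095 with 1 array left out. The 4 lists became 0 with an estimated correlation and 0 with fry, and 1 to 6 with 1 array left out, where the lone array was assumed to vary like the others; without saline 5-8 the matrix list passed and without ProMyo 1-4 the tendon list. The replicate block gave 5 lists, the macrophage list added, and changed no other call. The macrophage list also passed with quantile normalization, the ribosome list without a filter, with the mean of probe sets and without saline 1-4, the slow fibre list with the 50th percentile filter, and the endothelial list without saline 1-4. The r between pools lay from 0.14 to 0.17. With the mean of probe sets 4 named genes reversed: Etfdh (-0.28), Ncam1 (-0.011), Smad3 (-0.23) and Dlst (-0.12), where other probe sets, some within the background controls, enter the mean. None of the 4 lists reversed, but the medians of 20 of the 33 other lists changed sign in at least 1 setting, 15 of them with 1 array left out. Values near the background controls limit what dim genes can show.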

Other observations

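The added lists of endoplasmic reticulum chaperones and of heat shock genes, and the median without 2 mitochondrial members, were chosen after the result was seen; the other lists were fixed beforehand. Several further groups of genes held single members apart from the rest. The neuromuscular junction list had a median of -0.02 (camera, adjusted p = 0.80), with Ncam1, an adhesion molecule that denervated and regenerating fibres express, at 1.00 ± 0.30 and Rapsn, which clusters acetylcholine receptors, at -0.82 ± 0.21; the next brightest probe set of Ncam1 read -0.56. The list of embryonic and regenerating fibres had a median of -0.16 (adjusted p = 0.67), which was 0.05 without the saline 1-4 array and -0.07 without the ProMyo 5-8 array, with Actc1 as its 1 member of at least 1.5-fold in both pools. The cell cycle list had a median of 0.07 (camera, adjusted p = 0.78). In it Top2a, Mki67 at 0.65 and Ccnd2 at 0.44 ± 0.18 stood above 0 in both pools. The next brightest probe set of Ccnd2 read -0.18. Mki67 started from a saline level within the background controls, so the size of its difference is uncertain. Endothelial markers had a median of 0.09 (adjusted p = 0.21), which was -0.01 without saline 5-8, 0.20 without saline 1-4, 0.04 without ProMyo 1-4 and 0.22 without ProMyo 5-8, with Robo4 at 0.69 ± 0.18 and Sox18 at 0.61 ± 0.24. In the calcium handling list, with a median of 0.05 (adjusted p = 0.80), Stim1, the calcium sensor of store-operated entry, stood at -0.72 ± 0.20 and Cacnb1 at 0.71 ± 0.24; the next brightest probe sets read -0.33 for Stim1 and -0.03 for Cacnb1.

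The remaining lists gave medians between -0.14 and 0.12 and did not pass camera's test. Of the 33 lists that camera did not call, 15 had a median that changed sign with 1 array left out, so the sign of these small medians is not settled; nerve and Schwann cells, for example, went to 0.05 without saline 5-8. Among markers of other cell types, the medians, with camera's adjusted p in parentheses, were -0.05 for adipocytes (0.47), -0.05 for satellite cells (0.80), 0.02 for smooth muscle and pericytes (0.80), -0.14 for nerve and Schwann cells (0.60), -0.06 for neutrophils and mast cells (0.78), 0.12 for lymphocytes (0.80) and 0.11 for red blood cells (0.78). Antigen presentation genes had a median of 0.11 (0.67) and interferon response genes 0.06 (0.80). In metabolism and signalling, lipid synthesis and storage had a median of 0.06 (0.80), glycolysis and glycogen 0.02 (0.80), regulators of mitochondrial biogenesis 0.04 (0.97), BMP signalling 0.10 (0.80), p53 and DNA damage 0.09 (0.78), and secreted muscle factors 0.04 (0.47). For glycolysis and for the mitochondrial regulators, camera's direction was down although the median was above 0. The test of lists by fry found none shifted one way on balance (smallest adjusted p = 0.51) and 3 changed in either direction, which were the fibroblast, citrate cycle and heat shock lists.

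The list of heat shock and endoplasmic reticulum stress had a median of 0.11 (camera, adjusted p = 0.80), and fry called it changed in either direction (adjusted p = 0.0037). Hspa5, the main chaperone of the endoplasmic reticulum, stood at 0.68 ± 0.17, while Hspb7 and Dnajb1, chaperones of the cytosol, stood at -0.78 ± 0.33 and -0.47 ± 0.20, and Hspa1a was within the background controls in both groups. A hypothesis is that chaperones of the 2 compartments may have moved apart as groups. The 15 other chaperones and folding factors of the endoplasmic reticulum had a median of 0.092, with 8 higher in both pools and 1 lower, which leaves the question open for them (camera, adjusted p = 0.20 among 39 lists; adjusted p = 0.95 with an estimated correlation). The 21 other measured heat shock genes, 2 of them mitochondrial, had a median of 0.074. Of these, 9 were higher in both pools and 1 lower (camera, adjusted p = 0.37). The 19 of the cytosol also had a median of 0.074, with 8 higher and 1 lower. Some of them (Hspa1b, Hspb1, Hspb8, Cryab, Bag3 and Hsph1) were also in the fixed list, as was Hsp90b1 of the chaperones. Hspb7, Dnajb1 and Hspa1a were left out, so these values speak against a lower cytosolic group only beyond those genes.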
